A study of Mus musculus with 6 samples.

How the data were processed

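The libraries were made by Smart-Seq2 from mouse 4-cell embryos and sequenced as paired ends on an Illumina HiSeq, per the labels' protocols. Reads were handled with cutadapt 1.16 and STAR and the mm10 build, per the submitters' processing notes; the tool that made the expression values and the annotation release are not given in the sources used here. The deposited values are FPKM per gene, per the file headers, with 2 decimals and 55335 genes for each of the 6 libraries. FPKM divides by transcript length and by the library's total, so a rise of abundant transcripts lowers the values of the rest.

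The design had named a count test for the case of counts, with limma on log values for the case of FPKM, and the second was used because the deposited files hold FPKM. Of the gene IDs 55154 matched GENCODE M21 (GRCm38, the same assembly as mm10) without their version, and 181 did not; 105 symbols were held by more than 1 ID. The depth was estimated from low values of genes with 1 transcript, where FPKM moves in steps of 1 fragment. It came to 23100000, 23700000 and 22200000 fragments in Con replicates 1 to 3 and 23300000, 22800000 and 25300000 in DRB replicates 1 to 3, with 73.1% to 82% of the low values within 0.15 of a whole number. Whole counts were not rebuilt for all genes, since the length used for each gene is not known.

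Genes with an FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, the group as the single term, all 6 libraries in the fit, two-sided p-values and Benjamini-Hochberg adjustment, called below 0.05. Fold changes are DRB over Con on that scale, with limma's moderated standard error. Measures of whole libraries were compared by an exact two-sided permutation test. No source says that the replicates came from separate matings or cultures, so p-values measure only the spread between these samples, which may be technical.

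Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members, 27 in all, were tested with camera at its preset correlation of 0.01. The rule took 3 sets of genes. The first set was the 15 highest and 15 lowest log2 fold changes among called genes with a mean of at least 20 FPKM in the higher group, no overlap between groups and a symbol that is not a bare model or clone name. The second was up to 2 higher and 2 lower called members of each list, or else its 2 most abundant tested members, and the third was 18 genes named in advance. Arg2, Tdpoz1, Spz1, Psmc4, Dusp1 and Dusp5, and the other genes named in the closing section, were chosen after their values were seen.

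The fits were tested on simulated data made from the real means and spreads of the 11893 tested genes, with 200 genes changed in each of 5 runs. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes was not measured. Of genes changed by 1, 2, 3 and 4 on the log2 scale, 3.6%, 55.2%, 79.6% and 94% were recovered, and 3.5% of the calls were false. In the simulation camera called the 1 shifted list and 0 of 29 unchanged lists, but the simulated genes were independent of each other, so this does not test the preset correlation. In the real libraries camera called 0 to 6 lists in the 9 other splits, with 3 or more in 6 of them. Each of those splits mixes the groups unevenly and keeps part of any group difference, so they do not measure false calls. By the shares recovered in the simulation, small changes are mostly missed with 3 libraries per group.

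Alternatives fixed in advance were a pseudocount of 0.1, no filter, the replicate number as a block, leaving out each library, a threshold of 0.01, a test against a log2 fold change of 1, leaving out mitochondrial genes, and for the lists an estimated correlation and fry. Added after seeing the data were median-of-ratios, upper-quartile and common-total scaling, a minimum of 5 FPKM, leaving out genes with transcripts under 200 bases, and removing a GC trend from each library. Count tests were not run, because the deposited values are not counts. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.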

Results

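RNA was measured in mouse 4-cell embryos by Smart-Seq2, a method that amplifies full-length cDNA from very small samples with an oligo-dT primer. The libraries form 2 groups of 3, control embryos (Con) and embryos treated with DRB. DRB is a nucleoside analogue that blocks RNA polymerase II elongation by inhibiting CDK9 kinase. Zygotes received 20 µM DRB from 6 h after fertilization for 20 h, were washed, and grew for another 26 h without the inhibitor. The sample labels do not say whether Con embryos received the vehicle, and no culture times are recorded for Con here. The number of embryos behind each library is not given in the sources used here. The depth estimated from the low FPKM values was 22200000 to 25300000 fragments per library, so the groups were sequenced about equally deeply. Pearson's r of log2 values between libraries was 0.935 to 0.944 within Con, 0.909 to 0.937 within DRB and 0.869 to 0.915 between the groups. DRB replicate 1 stood farthest from the rest, and Con replicate 1 had 22102 genes above 0 FPKM, against 18485 to 19895 in the others.

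The comparison asks how the transcriptome of the 4-cell embryo differs after transcription was blocked from the zygote onward and then released. A set of genes of the 2-cell stage was higher in DRB embryos by a test that uses a preset correlation between genes (adjusted p 3.16e-10), a call lost with an estimated correlation (adjusted p 0.864). Among them was Zfp352, a zinc-finger gene of early cleavage, which rose from 4.44 ± 2.92 to 44.3 ± 9.47 FPKM (SD, n = 3 per group). Scd3, a stearoyl-CoA desaturase, rose from 1.88 ± 1.56 to 89.5 ± 14.8 FPKM, and Gadd45a, a growth arrest and DNA damage gene, rose from 2.84 ± 0.322 to 36.6 ± 17.7 FPKM. Pramel6, a member of a multi-copy family, fell from 360.3 ± 130.5 to 73.5 ± 11.9 FPKM. Genes of the respiratory chain, the proteasome and the cytosolic ribosome were lower as groups by the same test, and those calls too were lost when the correlation was estimated from the data (adjusted p 0.864, 0.864 and 0.909).

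Of 11893 genes tested with limma, 295 changed at a Benjamini-Hochberg adjusted p below 0.05, 182 higher and 113 lower in DRB. All 295 had the 3 DRB libraries entirely above or below the 3 Con libraries; 23.8% of all tested genes did, where chance gives 10%. An unadjusted limma p below 0.05 was reached by 2150 of the 11893, the share beside which list counts at that threshold are to be read. The smallest called change was 1.17 on the log2(FPKM + 1) scale, on which changes of low genes are understated. The called genes included 101 higher and 84 lower of 9420 protein-coding genes, 18 higher and 9 lower of 415 lincRNAs, and 37 higher and 6 lower of 1182 pseudogenes. The rest were 9 higher and 6 lower of 249 small or mitochondrial RNAs, 16 higher and 8 lower of 618 genes of other types, and 1 higher of 9 unmatched genes. The share of higher genes was 61.7%, and it was 72% with mitochondrial genes left out and 72.7% with median-of-ratios scaling, chosen after seeing the data. Without DRB replicate 1, 47 genes were called, without 1 of the other libraries 106 to 220, with a pseudocount of 0.1, 164, and with no filter on low values, 6. With transcripts under 200 bases left out, chosen after seeing the data, 391 were called.

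**Figure D1:**
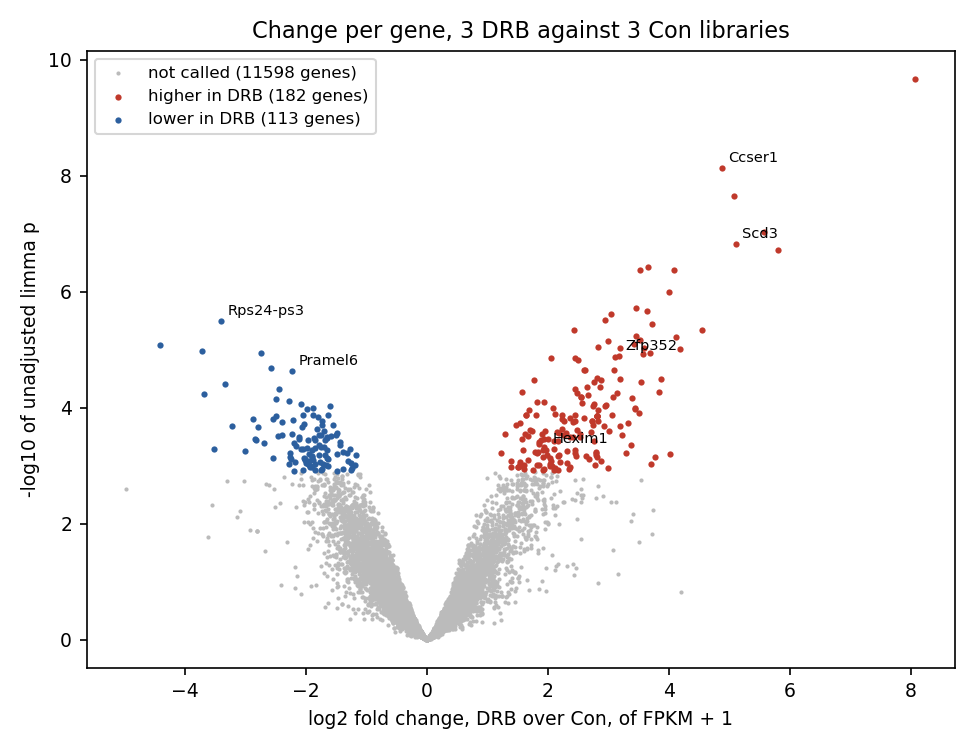
Each point is 1 of 11893 tested genes, with the log2 fold change of FPKM + 1 (DRB over Con, 3 libraries each) on the x axis and -log10 of the unadjusted limma p on the y axis. Red points are the 182 genes higher in DRB and blue points the 113 lower at adjusted p below 0.05.

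Among the genes with the largest rises, Ccser1 on chromosome 6 (61180324 to 62382865, GRCm38) went from 4.44 ± 0.32 to 163.1 ± 41.4 FPKM (SD, n = 3; log2 fold change 4.88 ± 0.31 SE, limma adjusted p 4.39e-05). Scd3 on chromosome 19 (44203269 to 44244016) had a log2 fold change of 5.11 ± 0.44 SE with a limma adjusted p of 0.00036. Scamp1, a carrier protein of secretory membranes, rose by 3.04 on the log2 scale, Gcnt2, a branching glycosyltransferase, by 3.52, and Calml4, a calmodulin-like gene, by 3.45. Gadd45a and Zfp352 rose by 3.19 and 3.18. Each of these 7 genes was also called in all 6 fits that left out 1 library. AA414992 rose by 4.55, Ankrd22 by 3.84, Prex2 by 3.15, the small nucleolar RNA Snord14e by 3.77 and the pseudogene Rpl23a-ps4 by 3.38; reads of a pseudogene cannot be assigned to it with certainty. Of the 6 fits that left out 1 library, AA414992 was called in 6, Ankrd22 and Prex2 in 5, Rpl23a-ps4 in 3 and Snord14e in 1. The mitochondrial tRNA gene mt-Td and the small nucleolar RNA Snord104 are 70 bases long and were listed at 0 in the 3 Con libraries. In DRB replicates 1 to 3, mt-Td stood at 187.4, 249.4 and 414.3 FPKM and Snord104 at 37.5, 124.7 and 34.5 FPKM. In each DRB library the mt-Td value was close to a whole multiple of the Snord104 value. For genes this short the values move in large steps of 1 fragment, so Snord104 may rest on very few fragments and mt-Td on few.

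Among the genes with the largest falls, Rps24-ps3, a pseudogene of a ribosomal protein, went from 381.1 ± 40.1 to 40.3 ± 27.5 FPKM (SD, n = 3; limma adjusted p 0.00254). Pramel6 on chromosome 2 (87506565 to 87510872) had a log2 fold change of -2.22 ± 0.32 SE (limma adjusted p 0.00672). Ddah1, which breaks down methylated arginine, fell by 2.45 on the log2 scale, and Ddt, the D-dopachrome tautomerase, fell by 2.27. Etfb, a subunit of the electron transfer flavoprotein, fell by 2.22, and Tecr, an enoyl-CoA reductase of fatty acid elongation, fell by 2.80. Commd4, Ppil3, Bc1, Cnmd, Dgkeos and Yif1a fell by 3.22, 3.00, 2.87, 2.69, 2.54 and 2.40. Vpreb3, Hmga2, an architectural chromatin protein, and Triml2 fell by 2.19, 2.07 and 2.07. Of these 15 genes, Rps24-ps3 and Pramel6 were called in all 6 fits that left out 1 library, Ddah1 and Bc1 in 5 and Ddt in 4. Etfb, Tecr and Commd4 were called in 3, Ppil3, Cnmd and Triml2 in 2, and Dgkeos, Yif1a, Vpreb3 and Hmga2 in 1.

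The list of 2-cell transient genes had 25 tested members, of which 6 were higher and 0 lower over all genes tested, and 8 were higher adjusted over the list alone. In all, 24 of the 25 had a positive log2 fold change, with a median of 1.22, and camera called the list higher (adjusted p 3.16e-10). That call was lost with an estimated correlation, where adjusted p was 0.864. The 6 called members were Zfp352, Pramef25, Gm5662, Arg2, Tdpoz1 and Spz1. Arg2, a mitochondrial arginase, rose from 3.13 ± 3.41 to 24.6 ± 5.86 FPKM, Tdpoz1 from 4.54 ± 3.22 to 24.9 ± 2.93 FPKM and Spz1 from 13.7 ± 4.21 to 86.5 ± 57.1 FPKM (SD, n = 3). Pramef25 rose from 0.867 ± 0.125 to 25.3 ± 22.8 FPKM and Gm5662 from 17.7 ± 3.09 to 263.8 ± 247.2 FPKM. Tdpoz1, Pramef25 and Gm5662 belong to multi-copy families whose reads may be split between copies. Of the 6 fits that left out 1 library, Pramef25 and Gm5662 were called in 5, Arg2 and Spz1 in 3 and Tdpoz1 in 2. Zscan4d, of the Zscan4 family of the 2-cell stage, stood at 5.12 ± 2.12 FPKM in Con and 8.96 ± 9.11 FPKM in DRB (limma adjusted p 0.823). Duxf3, the activator of 2-cell genes, did not reach the filter and was at most 0.41 FPKM in any library. The control libraries differed among themselves, with a median log2 value over the list of 3.48, 2.24 and 1.63 in Con and 3.89, 4.78 and 3.98 in DRB.

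**Figure D2:**
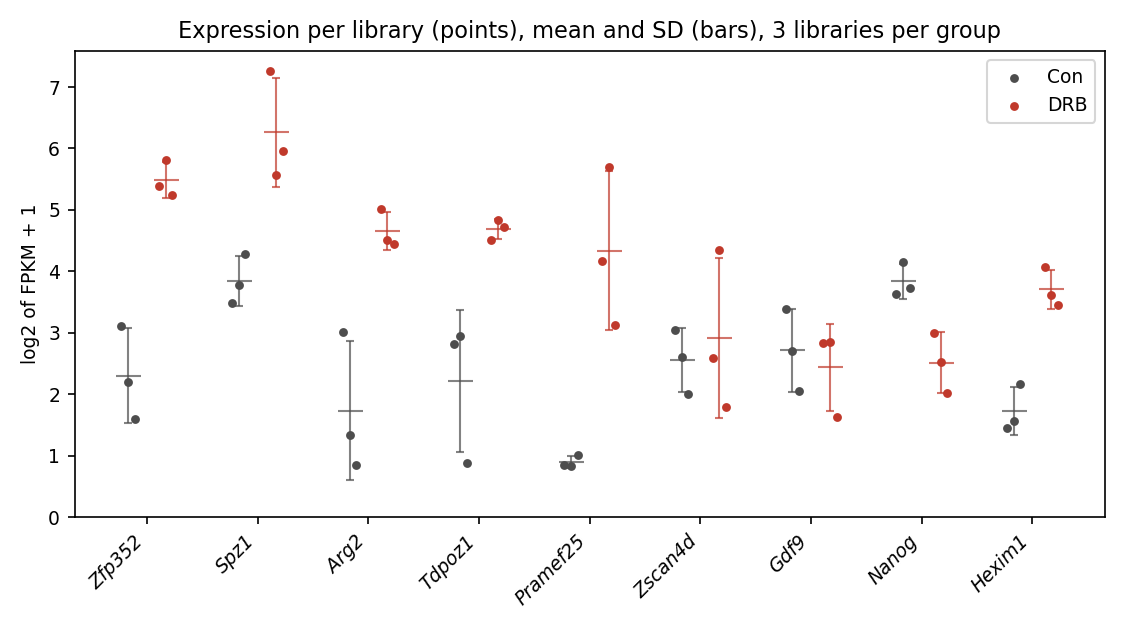
Points give log2 of FPKM + 1 in each library for 9 genes, grey for Con and red for DRB, with bars for the mean and SD of 3 libraries. The DRB points of Zfp352, Spz1, Arg2, Tdpoz1, Pramef25 and Hexim1 all lie above the Con points, those of Nanog lie below, and those of Zscan4d and Gdf9 overlap.

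Camera called 2 other lists higher. All 13 mitochondrial genome mRNAs had positive log2 fold changes with a median of 0.45 (camera adjusted p 0.00152, and adjusted p 0.864 with an estimated correlation), and 0 passed the limma gene test (2 at an unadjusted p below 0.05). With a GC trend removed from each library, chosen after seeing the data, this list's median was 0.25 and it was not called (camera adjusted p 0.0871). The most abundant, mt-Cytb and mt-Atp6, stood at 67457 and 60937 FPKM in DRB against 41541 and 42493 FPKM in Con. Mitochondrial genes took 16.97% ± 4.15 of all FPKM in Con and 25.3% ± 1.25 in DRB (SD, n = 3), an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Of 10 tested immediate early genes 1 was higher, and 3 were higher adjusted over the list alone, with a median log2 fold change of 0.46 (camera adjusted p 0.00469, and adjusted p 0.864 with an estimated correlation). The member called was Ier5, which rose from 0.58 ± 0.106 to 6.44 ± 2.38 FPKM; Dusp1 and Dusp5, phosphatases of MAP kinases, had log2 fold changes of 1.92 and 1.93 (limma adjusted p 0.0624 and 0.0842). Ier5 was called in 0 of the 3 fits without 1 library in which it was tested. This list was not called without DRB replicate 1 or without DRB replicate 3, where its highest adjusted p was 0.0637.

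The lists called lower were the nuclear-encoded respiratory chain, the proteasome and the cytosolic ribosomal proteins. In the respiratory chain 2 of 70 tested members fell and 12 fell adjusted over the list alone, with a median log2 fold change of -0.44 (camera adjusted p 4.78e-06, and adjusted p 0.864 with an estimated correlation). Ndufs7, of complex I, fell from 63.7 ± 21.5 to 18.4 ± 1.68 FPKM, and Uqcr11, of complex III, from 237.6 ± 58.8 to 79.6 ± 17.3 FPKM (SD, n = 3). In the proteasome 3 of 42 fell and 8 fell adjusted over the list alone, with a median of -0.46 (camera adjusted p 6.46e-05, and adjusted p 0.864 with an estimated correlation). The 3 were Psmg3, an assembly chaperone, Psmb3, of the core particle, and Psmc4, an ATPase of the regulatory particle, with log2 fold changes of -1.73, -1.63 and -1.32. Of the 6 fits that left out 1 library, Ndufs7 and Psmc4 were called in 0, Psmg3 and Psmb3 in 2 and Uqcr11 in 3. Of 79 cytosolic ribosomal protein genes 0 passed the limma gene test over all genes or adjusted over the list alone. At an unadjusted limma p below 0.05, 10 were lower and 0 higher, a smaller share than that of all tested genes (2150 of 11893). Of the 79, 4 had a positive sign and the median was -0.37 (camera adjusted p 1.18e-05, and adjusted p 0.909 with an estimated correlation). Rpl41 and Rps27, the most abundant, had log2 fold changes of -0.02 and -0.22, and that of Rpl41 turned positive under several scalings. The medians of the 3 lists relative to all tested genes were -0.35, -0.37 and -0.28. In Con replicates 1 to 3 the median log2 value was 6.98, 7.11 and 7.11 for the respiratory chain, 7.7, 7.2 and 7.26 for the proteasome and 10.82, 10.58 and 10.45 for the ribosomal proteins. In DRB replicates 1 to 3 it was 6.31, 6.56 and 7.15, then 6.67, 6.61 and 6.81, and 10.1, 10.33 and 10.55. DRB replicate 3 thus lay above all Con libraries for the respiratory chain and above Con replicate 3 for the ribosomal proteins. The ribosomal proteins took 13.7% ± 0.73 of all FPKM in Con and 10.9% ± 0.803 in DRB, with an exact permutation p of 0.1. Random lists matched on transcript length, GC content and expression had a median of -0.33 for the ribosomal proteins, close to the value observed.

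**Figure D3:**
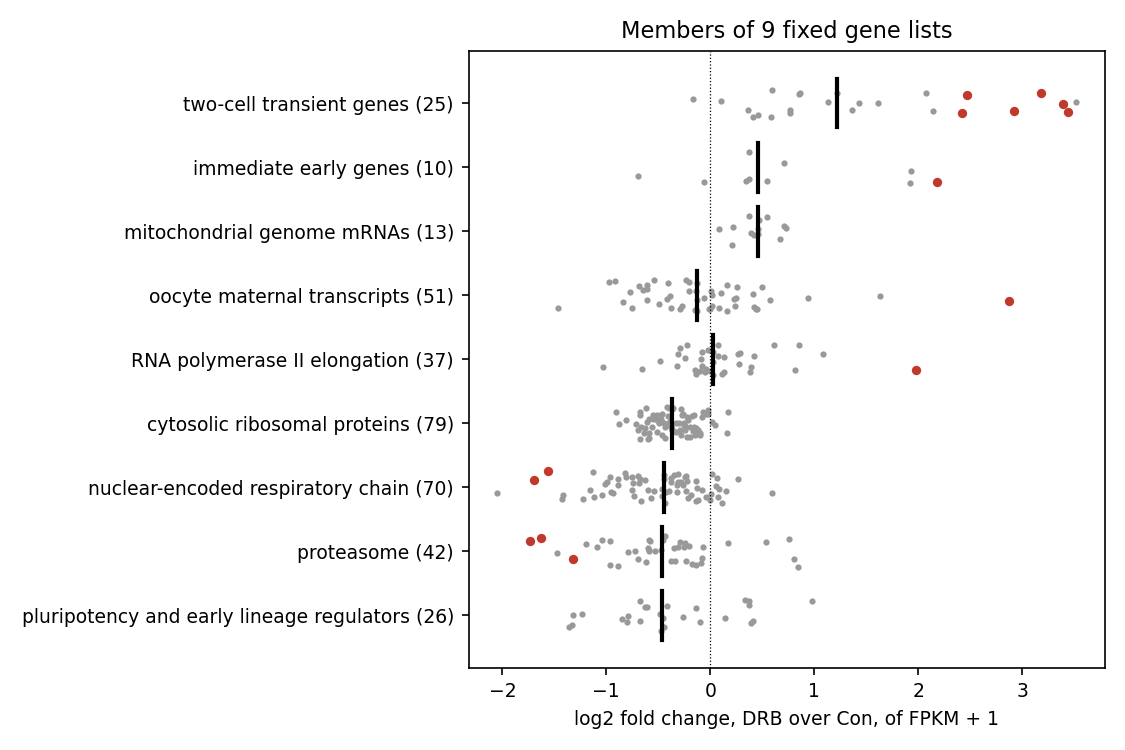
Points give the log2 fold change of FPKM + 1 (DRB over Con, x axis) of each tested member of 9 lists, with the number of members in parentheses and a black bar at the median. Red points passed the limma test over all genes; the median was 1.22 for the 2-cell transient genes and -0.46 for the proteasome.

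The remaining 21 lists with enough members were not called by camera (adjusted p 0.0687 to 0.933). Of 26 tested pluripotency and early lineage regulators 0 passed the limma gene test over all genes or adjusted over the list alone, 9 had an unadjusted p below 0.05, and 7 had a positive sign (median -0.47, camera adjusted p 0.1). Nanog stood at 13.5 ± 2.90 FPKM in Con and 4.93 ± 1.98 FPKM in DRB (limma adjusted p 0.115), and Nr5a2 at 70.3 ± 17.02 and 52.9 ± 15.2 FPKM. Pou5f1, Sox2 and Cdx2 did not reach the filter. Of 51 oocyte maternal transcripts 1 was higher, Oosp3, from 18.3 ± 9.52 to 182.4 ± 167.9 FPKM, and the list had a median of -0.13 (camera adjusted p 0.933). Gdf9 and Zp3, an oocyte growth factor and an egg coat protein, had log2 fold changes of -0.28 and -0.49 (limma adjusted p 0.836 and 0.43). In the maternal mRNA decay machinery 1 of 33 members rose, the nuclear poly(A)-binding protein Pabpn1, by 1.80 on the log2 scale, while Btg4 was at 25.5 ± 9.82 and 25.7 ± 8.99 FPKM. In the RNA polymerase II elongation list 1 of 37 members rose, Hexim1, an inhibitor of the CDK9 complex, from 2.40 ± 0.959 to 12.3 ± 3.08 FPKM (limma adjusted p 0.0323). Hexim1 was called in 1 of the 6 fits without 1 library, Oosp3 in 2 and Pabpn1 in 3. Cdk9 and Polr2a had log2 fold changes of -0.04 and 0.03 (limma adjusted p 0.97 and 0.981).

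Single members passed in 4 further lists. Ppp1r15a, a phosphatase subunit of the integrated stress response, rose by 1.82 on the log2 scale. Imp4 of ribosome biogenesis fell by 1.78, the splicing factor Prpf31 by 1.99 and the kinetochore protein Spc24 by 1.66. Of the 6 fits without 1 library, Ppp1r15a was called in 4, Prpf31 in 3, Imp4 in 1 and Spc24 in 0. Among 26 p53 targets 0 passed the limma test over all genes (7 at an unadjusted p below 0.05) and 1 was higher adjusted over the list alone, with Cdkn1a at 43.4 ± 19.9 and 49.6 ± 5.86 FPKM and Mdm2 at 41.9 ± 3.01 and 53.5 ± 10.9 FPKM. Hspa1b, a heat shock protein, was at 0.577 ± 0.621 and 3.04 ± 2.01 FPKM (limma adjusted p 0.176), and Xist at 11.2 ± 10.02 and 10.7 ± 6.76 FPKM. Markers of other cells gave no call: 4 cumulus cell markers, 2 sperm markers and 6 blood cell markers were tested, and 0 passed the limma test over all genes or at an unadjusted p below 0.05. The medians of the lists were 0.05, 0.15 and 0.47, with 4 of the 6 blood cell markers positive (camera adjusted p 0.849). Gja1 and Amhr2 of the first list had log2 fold changes of -0.61 and 0.25, Ldhc and Odf2 of the second -0.32 and 0.62, and Hba-a1 and Hba-a2 of the third -0.70 and -0.60.

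Gene length was compared with the change because DRB acts on elongation. Spearman's rho across 11884 genes, which are not independent replicates, was 0.053 for gene length (exact permutation p of 0.8 over the 10 splits of the libraries) and -0.004 for the number of exons. Genes under 1 kb had a median log2 fold change of -0.09 and genes over 50 kb of -0.003, against -0.17 for genes of 5 to 20 kb. Higher calls made up 3.07% of genes under 1 kb and 1.02% of genes over 50 kb, and lower calls 1.39% and 0.33%.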

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

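The scalings, the minimum of 5 FPKM, the limit of 200 bases and the GC correction were chosen after seeing the data. All called genes kept their sign wherever they were tested in these settings, but calls were lost in several, and the cause was not tested. The planned count tests and normalizations for counts were not run, since the values are FPKM. Counts of genes changed, higher and lower were 295, 182 and 113. They were 164, 113 and 51 with a pseudocount of 0.1, 6, 6 and 0 with no filter (27554 genes tested), 50, 43 and 7 at adjusted p below 0.01, and 27, 24 and 3 against a log2 fold change of 1. Leaving out mitochondrial genes gave 264, 190 and 74 and shifted the median of all genes by 0.11, and median-of-ratios scaling gave 315, 229 and 86. With transcripts under 200 bases left out 391 genes were called, among them all 272 of the main calls that were tested there. The minimum of 5 FPKM gave 316 changed, upper-quartile scaling 305, a common total 287 and the GC correction 259. Without 1 library the counts ranged from 47 to 220 changed, 34 to 139 higher and 13 to 81 lower. They were 148 without Con replicate 1, 110 without Con replicate 2, 106 without Con replicate 3, 47 without DRB replicate 1, 151 without DRB replicate 2 and 220 without DRB replicate 3. In all 6 of these fits 36 of the genes stayed called, 30 higher and 6 lower.

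With the replicate block the counts were 171 changed, 127 higher and 44 lower, and 160 of the 171 were among the 295. No source says what the numbers mark. Deviations of libraries with the same number correlated at -0.051 to 0.053, which shows no pairing but cannot exclude a shared mating, day or batch.

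Of 6 lists called, 3 higher and 3 lower, 0, 0 and 0 stayed with an estimated correlation, and 0, 0 and 0 with fry (adjusted p 0.198 for each of the 6). Without 1 library 2 to 5 lists were called higher. The immediate early genes were lost without DRB replicate 1 and without DRB replicate 3 (highest adjusted p 0.0637). The mitochondrial genome mRNAs were lost with the GC trend removed, where camera adjusted p was 0.0871. Their median went from 0.45 (SD 0.2 between members) to 0.25 (SD 0.19), so the change was smaller while the spread between members was about the same. Gene length had a rho of 0.053, and of -0.012 with no filter and -0.02 to 0.114 without 1 library (-0.02 without DRB replicate 1, 0.114 without DRB replicate 3).

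Among alternatives for named genes 288 of 1799 lost and 4 gained a call, and for lists 15 of 482 lost and 7 gained one, with the sign kept. These totals include genes and lists without a call in the main fit, which had none to lose. The shares lost therefore understate how often a call was lost. Signs turned in 52 of 1799 alternatives for named genes and 30 of 482 for lists, none of them called in either setting. By setting, the log2 fold changes that turned were Dppa4 0.007, Rpl41 0.084, Orc6 0.031 and Cdk9 0.068 with median-of-ratios scaling, and Dppa4 0.032, Rpl41 0.108, Orc6 0.056, Fdft1 0.009 and Cdk9 0.093 with mitochondrial genes left out. They were Rpl41 0.059, Orc6 0.006 and Cdk9 0.043 with upper-quartile scaling, Hsp90aa1 -0.001 with a common total, and Rpl41 0.124, Hsp90aa1 -0.093, Dppa3 -0.025, Btg4 -0.106 and Cdk9 0.012 with the GC trend removed. Without 1 library the ranges were Obox8 -0.59 to 0.27, Dppa4 -0.25 to 0.019, Cycs -0.20 to 0.44, Orc6 -0.18 to 0.12, Dppa3 -0.085 to 0.36, Trim28 -0.18 to 0.34, Fdft1 -0.41 to 0.25, Gdf9 -0.61 to 0.13, Rpl41 -0.20 to 0.26, Hsp90aa1 -0.18 to 0.22, Stat2 -0.029 to 0.21, Polr2a -0.21 to 0.31, Xist -0.76 to 1.15, Btg4 -0.25 to 0.33, Epcam -0.12 to 0.48, Rps27l -0.35 to 0.088, Zscan4d -0.36 to 0.92 and Cdk9 -0.43 to 0.20.

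For lists, the adjusted p where the direction turned was 0.967 for ribosome biogenesis and 0.905 for the spliceosome with median-of-ratios scaling, 0.97 for both with mitochondrial genes left out, and 0.924 for the spliceosome with upper-quartile scaling and 0.906 at 5 FPKM. It was 0.96 for DNA methylation with a common total, 0.847 for apoptosis, 0.95 for heat shock proteins and 0.909 for retrotransposon control with fry, 0.915 for apoptosis and 0.915 for cholesterol synthesis with no filter, and 0.995 for Obox with the GC trend removed. Without 1 library the adjusted p ranged from 0.574 to 0.976 for maternal transcripts, 0.59 to 0.976 for ribosome biogenesis, 0.758 to 0.976 for the spliceosome, 0.881 to 0.995 for apoptosis, 0.594 to 0.883 for Obox, 0.758 to 0.995 for retrotransposon control, 0.881 to 0.976 for DNA methylation, 0.557 to 0.956 for blood cells and 0.614 to 0.954 for epithelial genes.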

Other observations

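The groups and genes in the first 2 paragraphs were chosen after their values were seen. Of 78 tested mitochondrial ribosomal protein genes 71 had a negative log2 fold change, with a median of -0.66, and 4 fell over all genes tested. The 4 were Mrps27, Mrps31, Mrpl17 and Mrpl41, with log2 fold changes of -2.16, -2.04, -1.58 and -1.44. The family was 1 of 7 tested after its called members were seen, of which camera called 4 and, with an estimated correlation, 0; its camera adjusted p was 1.27e-09, and adjusted p was 0.209 with an estimated correlation. Of 17 citrate cycle enzymes 2 fell, Mdh2 from 215.1 ± 22.7 to 71.2 ± 16.1 FPKM and Suclg1 from 29.1 ± 0.481 to 8.14 ± 0.839 FPKM, and 1 rose, Ogdh from 5.82 ± 0.895 to 18.7 ± 0.561 FPKM (SD, n = 3). Exosc1 and Exosc4, of the RNA exosome, fell by 1.49 and 1.63 on the log2 scale. Actb, the cytoplasmic actin often used as a reference gene, fell from 340.4 ± 73.3 to 101.9 ± 49.0 FPKM (limma adjusted p 0.0318). Of the 6 fits that left out 1 library, Mdh2 was called in 4, Suclg1 and Mrps31 in 2, Mrps27, Mrpl17, Exosc1 and Actb in 1 and Mrpl41, Ogdh and Exosc4 in 0.

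Genes higher in DRB lay near each other in the genome more often than most random sets. The random sets were not matched on gene family, and neighbouring copies with slightly different values were counted separately. Reads shared between such copies were therefore not told apart from a rise of each gene. With identical value profiles counted once, and 1 mitochondrial gene and 1 gene without coordinates left out, 43 of 172 genes higher in DRB had another within 500 kb, where random sets of tested genes had a median of 25, and 40 of 10000 sets reached 43. For the 113 lower genes the number was 18, against a median of 11, and 841 of 10000 sets reached it, so it lay within the random range. On chromosome 3 (93669333 to 94199802, GRCm38) 5 of 17 tested genes rose, Tdpoz1 with Gm9117, Gm9125, Gm10696 and Gm5286. On chromosome 12 (87494721 to 88274500) 5 of 23 rose, with 4 distinct profiles, among them Gm2016 and Gm5662. On chromosome 2 (83915079 to 83993045) 7 of 7 rose, though these had only 3 distinct profiles. In all, 13 called genes shared their 6 values with another tested gene. On chromosome 10 (118243800 to 118445892) 3 of 8 rose, Ifng with Gm9029 and Gm9030. Ifng was listed at 0 in the 3 Con libraries and at 6.73, 16.8 and 8.09 FPKM in DRB replicates 1 to 3. Tob1, an antiproliferative gene, rose from 4.55 ± 1.94 to 42.2 ± 8.88 FPKM. The median SD of log2 values was 0.38 in Con and 0.48 in DRB.

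In what follows, the tests of paralogs, of displacement by mitochondrial transcripts and of other splits were chosen after the results were seen, as was the division of the 2-cell list into single-copy and multi-copy members. The first pattern is the rise of 2-cell genes. The values argue against 1 scaling factor per library as the cause. The list's median was 1.38 with median-of-ratios scaling, which was chosen after the data were seen, and 1.35 with mitochondrial genes left out. Both lay above the bound of 1, which was set before this test but for a pattern already seen. Shared reads predict no rise in the 8 members outside multi-copy families, whose median lay 1.33 above that of all genes. That passed the bound of 3 standard errors between genes, 1.28, by a narrow margin. The members were measured in the same 6 libraries and correlate (estimated at 0.388 for the whole list). This standard error is therefore too small, and the test does not decide. Shared reads stay open for the 17 multi-copy members too. FPKM was summed over the genes of each family found by symbol, 5 for Tdpoz and 4 for the group of Gm5662. Any copies under other symbols were left out, so reads moved to or from them were not tested. The sum was above all Con libraries in all DRB libraries, with a log2 ratio above 1, in 3 of 7 families. These were Usp17l, Tdpoz and the Gm5662 group, with ratios of 2.13, 1.12 and 2.98. The ratio was 1.55 for Tcstv and 0.56 for Zscan4, with overlap between the groups, and -0.64 for Obox and -0.57 for Pramef and Pramel. Those last families hold most of the FPKM. The sum over the genes of all 7 families found by symbol (-0.33, against 2.25 over the list members alone) mainly reflects Obox, Pramef and Pramel. An earlier point of development may be the cause and was not excluded: maternal transcripts had a median of -0.038 relative to all genes, neither above 0 nor called lower. The early lineage regulators went in the direction it predicts, with 7 of 26 positive and a median of -0.47, but were not called (camera adjusted p 0.1), so a delayed embryo and a lasting effect of the inhibitor cannot be told apart here.

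The second pattern is the lower respiratory chain, proteasome and ribosomal protein mRNAs. Displacement by the larger mitochondrial share lowers all nuclear genes of a library by the same factor. With mitochondrial genes left out the 3 list medians went from -0.44, -0.46 and -0.37 to -0.31, -0.34 and -0.24, so displacement may account for the part that was removed and not for the rest as observed. That rest was not beyond the spread between libraries in all lists. The DRB minus Con difference of library medians, relative to all nuclear genes, was 1.01, 3.42 and 1.09 standard errors in size for the respiratory chain, the proteasome and the ribosomal proteins, and with each gene centred first 1.39, 2.07 and 1.5. With 3 libraries per group, displacement together with variation between libraries cannot be told apart from a further fall of these lists. Transcript length, GC content and expression could account for part: 25 of 10000 matched random lists had a median at or below that of the 3 lists pooled (-0.39, random median -0.25), which is between the bounds set before the test. Taken one by one, 5 of 10000 reached the proteasome's median, 87 the respiratory chain's and 1898 the ribosomal proteins'. The ribosomal proteins and other genes of like length, GC content and expression cannot be told apart by this test, and an effect of the treatment stays open for all 3.

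The third pattern is the change between the groups as a whole. Transcript length had a rho of 0.08 with the log2 fold change across genes, under the bound of 0.1 set in advance. Transcript GC content had a rho of -0.167, above that bound in size, and 1 of the 9 other splits had a larger one (0.236). With a smooth GC trend removed from each library 246 of the 295 genes stayed called (83.4%), though the list of mitochondrial genome mRNAs did not (camera adjusted p 0.0871), so GC content is unlikely to be the whole cause. The 6 libraries make 10 splits, too few for a share under 0.05. The real split called 295 genes and the highest of the others 4, and 1 of the 10 gave as many; for genes higher (182) and lower (113) the highest other count in 1 direction was 3, again with 1 of 10. For the fixed lists 2 of the 10 splits gave as many as 6, the other being Con 1, Con 2 and DRB 2 against the rest. The 9 other splits gave 0 to 6 lists, and 6 of them gave 3 or more. Each of these splits mixes the groups unevenly. Part of any group difference stays between its sides, and the rest widens the spread within them. Their counts of genes and lists therefore do not measure how many calls arise without a group difference. Camera calls at the preset correlation remain weak evidence, since all 6 were lost with an estimated correlation.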
